A study of Mus musculus with 18 samples.

How the data were processed

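RNA was measured in 18 libraries of 6 groups with 3 libraries each, all given as 1 batch. Per the labels' protocols, RNA was extracted with a Qiagen kit, polyA RNA was made into libraries and these were sequenced on a NovaSeqX Plus instrument. The 6 LLC libraries came from cells left untreated or irradiated with 4 Gy and collected 12 h later. The 12 MNP libraries came from marrow-derived cells kept for 24 h with LLC cells and sorted on Ly6C. The series text describes the EGFR+ mice as wild-type C57BL/6, whereas the sample labels describe them as carrying a floxed Egfr gene. Both descriptions leave Egfr in place, and the groups here follow the sample labels.

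The deposited count tables hold whole numbers of reads per gene for each library, made by the authors with no normalization. Per the submitters' processing notes, FastQC 0.12.1, STAR 2.7.10b, SAMtools 1.17, Subread 2.0.5, R 4.3.1 and DESeq2 (with no version) were used, on the mouse build mm10 (GRCm38). The role of each tool, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited normalized tables hold a signal that is the raw count divided by 1 size factor per library, which was tested by comparing both kinds of table. They keep 14270 genes for LLC cells and 15383 for MNPs, the latter those with a total of 40 counts or more. For LLC cells the rule is not given in the sources used here, and the size factors differ from those recomputed with DESeq2. The main results used the raw counts, and the normalized tables served for 1 alternative.

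Each raw table lists 24435 genes, of which 23204 carry a RefSeq symbol of GRCm38.p6. Another 13 are mitochondrial genes listed by RefSeq protein identifiers. Of the 24435 genes, 7360 had 0 counts in every LLC library and 5919 in every MNP library. The ribosomal precursor Rn45s took 0.523% of counts in LLC and 0.172% in MNP libraries. Library totals lay between 102402000 and 129513000 counts. Without strand, reads of antisense or overlapping genes cannot be separated, and reads of near-identical genes (Lyz1 and Lyz2, Ifit3 and Ifit3b, H2 genes) are uncertain. Gene positions are from RefSeq of that build, lengths from the longest GENCODE transcript.

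Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test with robust dispersion, TMM scaling, filterByExpr on the groups, and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05). Changes of 2-fold or more were also counted. The LLC fit held 6 libraries and 13161 genes, with a common biological coefficient of variation of 5.19%. The MNP fit held 12 libraries and 14700 genes, with 8.93%, because the 4 groups form 1 experiment and share an estimate of the spread. No replicate block was used. The comparisons were irradiated against untreated LLC cells, the AREG− against the AREG+ partner in MNPs of each genotype, EGFR− against EGFR+ MNPs with each partner, and the interaction of both factors. Log2 CPM and fold changes are those of edgeR.

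Gene lists, 35 in all, were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the 20 lists of the LLC or the 32 lists of the MNP experiment. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. Fry passed 11, 15, 18, 12, 12 and 1 lists in the order of the comparisons above. The lists cover ErbB ligands and receptors, p53 targets, homologous recombination, DNA replication, G2/M, interferon-stimulated and interferon-gamma-response genes, NF-kB targets, chemokines, secreted and senescence-associated factors, and mesenchymal and immediate-early genes. Others cover ERK-pathway outputs, the unfolded protein and integrated stress response (called stress response), hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, phagocytosis, immunosuppressive, pro-inflammatory and co-stimulatory, MHC class I and II, classical monocyte, macrophage, lipid and lysosome, and NRF2 genes. Markers cover LLC cells, neutrophils, dendritic cells, lymphocytes, mast cells with basophils and eosinophils, erythroid cells, myeloid progenitors, stroma and leukocytes.

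The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named a fixed panel of EGFR ligands, receptors and myeloid genes whatever their result. It also named, per comparison, the 8 largest rises and 8 largest falls past the threshold (6 each for the interaction) among genes of at least 5 CPM in the higher group and with no overlap between replicates. It left out predicted genes and clones. Per list it named up to 4 called members with the largest change, or 2 members of the highest CPM where none was called. From these, the examples in the text were picked after their calls without single libraries had been seen, mainly among genes whose call held.

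Alternatives fixed at that stage were DESeq2-type size factors, scaling by library size only, a filter of 5 CPM in at least 3 libraries, no filter, a replicate block, leaving out each library, only the compared groups in the fit, camera with an estimated correlation, and correlations over genes of at least 5 CPM. Other tools were DESeq2 1.42.0 (Wald test), limma-voom, and limma-trend on the deposited normalized counts with a pseudocount of 1. Another 4 were chosen after the data were seen. They left out LLC-dominant genes (at least 1 CPM in untreated LLC cells and 10 times the MNP mean or more), removed each library's trend on transcript length, left out the 3 libraries farthest from their groups, or did the latter 2 together. The trend was a lowess fit with a span of 0.3 over genes of at least 1 CPM, and 96.2% of tested genes had a length. LLC levels are those of untreated cells without any co-culture.

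The steps were tested on simulated counts with 200 of the genes changed. At 2-fold, 94% of changed genes were recovered for irradiation, 78% for the AREG− partner in either MNP genotype, 82% and 76% for the MNP genotype with the AREG+ and the AREG− partner, and 62% for the interaction. Among the calls 6.43% to 10.5% were false. A list of 30 genes shifted by 0.3 (log2) was recovered in each comparison, and 0 to 4 of 100 random lists had a p under 0.05. Removal of a simulated length trend took the calls from 53 to 0. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 served for tables and plots.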

Results

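The data comprised 18 polyA RNA-seq libraries of mouse cells in 6 groups of 3, from 2 experiments. The first measured Lewis lung carcinoma cells (LLC, a transplantable lung tumour line of C57BL/6 mice) carrying a red fluorescent protein, untreated or 12 h after 4 Gy of irradiation in culture. The second measured Ly6C+ mononuclear phagocytes (MNPs, cells of the monocyte and macrophage lineage) grown from bone marrow, kept with LLC cells for 24 h and sorted on Ly6C. The MNPs came from EGFR-positive mice (EGFR+) or from mice labelled EGFR-deficient (EGFR−), in which Cre recombinase expressed from the lysozyme M locus deletes Egfr in myeloid cells. Their tumour partner either expressed amphiregulin, a ligand of EGFR (AREG+), or was an LLC line with Areg knocked out (AREG−). The AREG− line was not sequenced here, and its other differences, if any, cannot be separated from AREG loss.

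The LLC libraries held 107872000 to 129513000 gene counts and the MNP libraries 102402000 to 128625000. The submitters call the 3 libraries of a group technical repeats, so the p-values measure only the spread between such repeats, not between cultures or animals. All libraries carry 1 batch label. Unless stated otherwise, n is 3 libraries per group, ± gives the standard error (SE) of a log2 fold change or the SD of CPM (counts scaled to library size), and fold changes are log2 fold changes. Counts of list members are over all genes tested, and the pair in square brackets after each is the count adjusted over the list alone. For a whole list, limma's camera test with a preset correlation was used. Its adjusted p is followed in round brackets by the range over the alternatives.

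Repeats of a group differed by more than sampling noise, with a chi-square per degree of freedom of 9.89 to 83.0 between pairs. In 3 MNP groups 1 library stood apart. Replicate 3 of EGFR− MNPs with the AREG+ partner gave 69.8 and 83.0 against the others, which gave 15.4 between them. Replicate 1 of EGFR+ MNPs gave 54.6 and 59.2 (others 15.5) with the AREG+ partner, and 56.0 and 65.9 (others 14.8) with the AREG− partner. The mitochondrial share of counts was 1.47% ± 0.047 in EGFR+ MNPs with the AREG+ partner and 1.23% ± 0.12 with the AREG− partner. In EGFR− MNPs it was 1.19% ± 0.24 and 1.05% ± 0.077, and the stand-apart replicate 3 had 1.47% against 1.02% and 1.07% in its group. Libraries also differed in how counts varied with transcript length. The fitted log2 difference between transcripts of 8000 and 1000 nucleotides was 0.25 ± 0.060 (SD) in EGFR+ MNPs with the AREG+ partner and -0.093 ± 0.077 with the AREG− partner. In EGFR− MNPs it was -0.045 ± 0.24 and -0.11 ± 0.091. Leaving out all 3 libraries that stood apart, removing the length trend and leaving out LLC-dominant genes were settings chosen after the data were seen, as were all counts of shared genes under other settings.

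**Figure D1:**
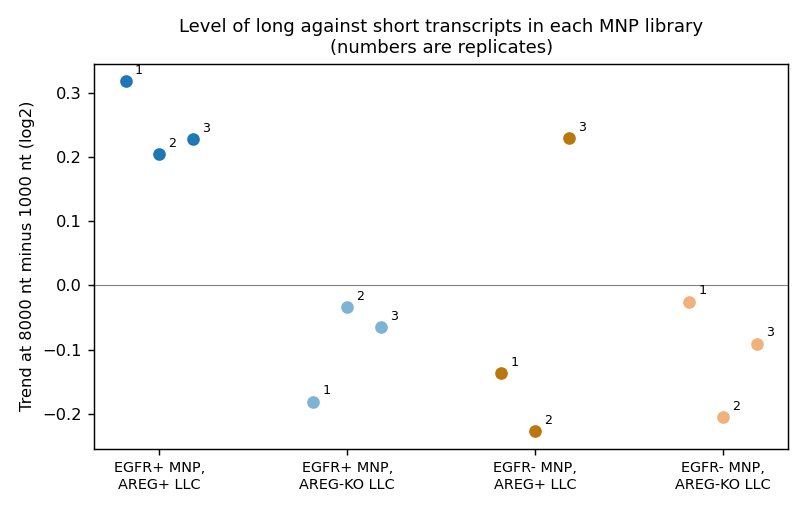
Fitted log2 difference between transcripts of 8000 and 1000 nucleotides (vertical axis) in each of the 12 MNP libraries, with 1 numbered point per replicate, by group. EGFR+ MNPs with the AREG+ partner lie at 0.25 on average, and replicate 3 of EGFR− MNPs with that partner lies at 0.23 against -0.14 and -0.23 in its group.

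The targeted genes were examined first. Areg lies on chromosome 5 (91139599 to 91148432, GRCm38) and Egfr on chromosome 11 (16752203 to 16913907). Lyz2, which encodes lysozyme M and is the site of the Cre insertion, lies on chromosome 10 (117277541 to 117282272). In EGFR+ MNPs Areg stood at 1.68 ± 0.23 CPM with the AREG+ and 1.78 ± 0.51 CPM with the AREG− partner, and in EGFR− MNPs at 2.35 ± 0.030 and 1.86 ± 0.082 CPM. These low levels in sorted MNPs do not check the tumour genotype. Egfr reached 2.75 ± 0.54 and 1.92 ± 0.35 CPM in EGFR+ MNPs and 2.32 ± 0.35 and 1.45 ± 0.11 CPM in EGFR− MNPs, against 49.2 ± 1.0 CPM in untreated LLC cells. The MNP genotypes did not differ in Egfr past the threshold with either partner (-0.25 ± 0.18 and -0.40 ± 0.18, edgeR adjusted p = 0.388 and 0.267). Counts over the whole gene include transcripts that lack a deleted part and any Egfr RNA of the tumour partner, so they do not check the label. Lyz2 separated the genotypes instead, falling from 12045 ± 575 to 29.3 ± 1.2 CPM with the AREG+ partner (-8.68 ± 0.21) and from 14630.4 ± 1558 to 35.7 ± 11 CPM with the AREG− partner (-8.68 ± 0.21; edgeR adjusted p = 6.0e-12 and 6.0e-12). By design every EGFR− library also carries Cre and a disrupted Lyz2 locus, so the loss of Egfr cannot be separated from these.

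**Figure D2:**
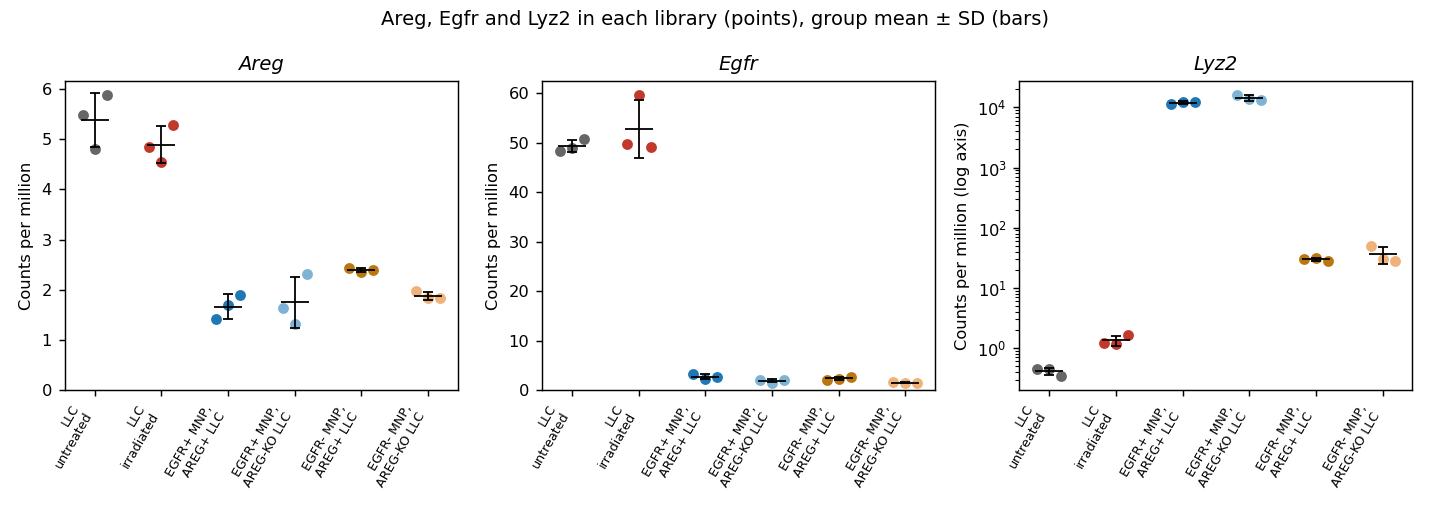
Counts of Areg, Egfr and Lyz2 in CPM of each library's total, before TMM scaling, on linear axes for Areg and Egfr and a log axis for Lyz2. Points are libraries and bars group means ± SD, and Lyz2 lies between 28.4 and 49.04 CPM in the 6 EGFR− libraries and above 11185 CPM in the 6 EGFR+ libraries.

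The first comparison asked how irradiation changes the transcriptome of the tumour cells, including the ligands of EGFR. At 12 h after 4 Gy, genes of the p53, interferon, chemokine, secreted-factor and MHC class I lists rose as groups, and genes of the hypoxia and cholesterol lists fell as groups, in camera with its preset correlation. None of these lists held with an estimated correlation (camera adjusted p = 0.117 to 0.563). Areg did not change past the threshold, at 5.38 ± 0.51 CPM in untreated and 4.90 ± 0.37 CPM in irradiated cells (log2 fold change -0.13 ± 0.10, edgeR adjusted p = 0.302; 95% interval of the fold 0.794 to 1.04). Of 13161 genes tested with edgeR's quasi-likelihood test, 2804 rose and 2655 fell at an adjusted p under 0.05, with a median absolute log2 fold change of 0.26. A change of 2-fold or more was reached by 448 rises and 22 falls, and 334 of these rises were in genes under 1 CPM. With a filter of 5 CPM the 470 changes were 29. The median log2 fold change was 0.27 in genes under 1 CPM, 0.14 at 1 to 5 CPM, -0.018 at 5 to 50 CPM and -0.026 above 50 CPM.

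Among genes of at least 5 CPM, Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 2.66 ± 0.062 to 7.94 ± 0.47 CPM (1.58 ± 0.095; edgeR adjusted p = 3.8e-09). Among the largest falls were Trib3 and Chac1, both targets of the stress regulator ATF4 (-0.93 ± 0.065 and -0.84 ± 0.11), and the Hedgehog receptor Ptch1 (-0.72 ± 0.057; edgeR adjusted p = 1.7e-08 to 1.1e-05). In each largest change named here and in the later comparisons, all 3 libraries of one group lay above all 3 of the other, which chance gives for 10% of unchanged genes. Egr1 rose by 1.30 ± 0.27 (edgeR adjusted p = 0.00737), but not without untreated replicate 1 (0.0612, in a range of 1.7e-08 to 0.0612 over its alternatives).

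Among the ErbB ligands and receptors, 3 of 12 rose and 1 fell [2 and 1], and the list did not pass (camera adjusted p = 0.519 (0.382 to 0.809, and 0.659 with an estimated correlation)). Erbb2, a receptor that pairs with EGFR, fell by 0.47 ± 0.065, and the ligand Btc rose from 0.749 ± 0.25 to 1.51 ± 0.18 CPM (edgeR adjusted p = 2.8e-05 and 0.00165). The ligand Ereg rose from 27.4 ± 0.57 to 30.1 ± 1.3 CPM (log2 fold change 0.14 ± 0.053, edgeR adjusted p = 0.0480). That call was lost in DESeq2 (0.0612), with DESeq2-type size factors (0.0525), with no filter on low counts (0.0653) and without untreated replicate 1 (0.156), 2 (0.0714) or 3 (0.127) or irradiated replicate 1 (0.131) or 3 (0.186), in a range of 0.0102 to 0.186. Hbegf, Tgfa, Egfr and Cd274 did not pass (edgeR adjusted p = 0.826, 0.767, 0.196 and 0.0949), and Epgn, at 0 to 10 counts per library, was not tested. Cd47, a signal against phagocytosis, rose by 0.14 ± 0.038 (edgeR adjusted p = 0.00856), though not without untreated replicate 2 (0.0522, in a range of 0.00310 to 0.0522).

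Of the p53 targets, 20 of 36 rose and 4 fell [20 and 5], with a median of 0.21 (camera adjusted p = 3.1e-05 (9.0e-06 to 0.117)). Trp53inp1 rose from 21.6 ± 1.0 to 46.6 ± 0.78 CPM and the cell-cycle regulator Ccng1 by 0.78 ± 0.039. The p53 ubiquitin ligase Mdm2 rose by 0.43 ± 0.041 and the cell-cycle inhibitor Cdkn1a by 0.30 ± 0.040 (edgeR adjusted p = 2.9e-10 to 2.4e-05 for the 4 genes). Cell-cycle and repair lists moved in both directions and did not pass (camera adjusted p = 0.427, 0.137 and 0.894). Of the G2/M genes 11 of 46 rose and 16 fell [11 and 17], of the DNA replication genes 12 of 38 rose and 5 fell [12 and 5] and of the homologous recombination genes 4 of 27 rose and 4 fell [4 and 4].

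Of the interferon-stimulated genes 32 of 44 rose and 1 fell [33 and 1], with a median of 0.49 (camera adjusted p = 9.3e-08 (2.0e-08 to 0.182)). The RNA sensor Ddx58 (RIG-I) rose from 20.03 ± 0.48 to 27.4 ± 1.9 CPM and the DNA sensor Ifi204 from 5.23 ± 0.23 to 8.46 ± 0.74 CPM (edgeR adjusted p = 1.6e-05 and 1.3e-05). Of the interferon-gamma-response genes 12 of 19 rose and 1 fell [13 and 1], and of the MHC class I genes 16 of 20 rose and 0 fell [16 and 0] (camera adjusted p = 0.00383 (0.00144 to 0.168) and 5.7e-07 (9.8e-08 to 0.117)). Among the chemokines 11 of 15 rose and 0 fell [11 and 0], including the monocyte attractant Ccl7 (from 38.1 ± 0.90 to 58.5 ± 5.3 CPM; edgeR adjusted p = 5.2e-07). Among the secreted and senescence-associated factors 19 of 38 rose and 4 fell [19 and 5], including the alarmin Il33 (1.01 ± 0.16; edgeR adjusted p = 1.0e-04). The latter lists had camera adjusted p = 1.6e-04 (9.0e-05 to 0.221) and 6.8e-04 (2.2e-04 to 0.253).

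Of the cholesterol synthesis genes 2 of 25 rose and 15 fell [2 and 18] (camera adjusted p = 2.0e-04 (1.9e-05 to 0.253)). The low-density lipoprotein receptor Ldlr fell by 0.42 ± 0.049 (edgeR adjusted p = 5.1e-06). Of the hypoxia and glycolysis genes 3 of 31 rose and 12 fell [3 and 12] (camera adjusted p = 0.0128 (0.00164 to 0.563)), the angiogenic factor Vegfa by 0.31 ± 0.046 (edgeR adjusted p = 5.4e-05). That list call was lost without untreated replicate 3 (0.0963) or irradiated replicate 2 (0.0596). Oxidative phosphorylation genes (12 of 38 rose and 3 fell [12 and 3]) and leukocyte markers (4 of 6 rose and 0 fell [4 and 0]) passed upward (camera adjusted p = 0.0445 (0.00417 to 0.641) and 0.0299 (0.0245 to 0.221)). The first call was lost without untreated replicate 1 (0.0527) or 3 (0.128) or irradiated replicate 1 (0.178) or 3 (0.0722), the second with no filter on low counts (0.0568). In all 10 lists that passed, the highest p of the range was that with an estimated correlation, so none held there.

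The other 6 lists did not pass. Of the stress-response genes 8 of 31 rose and 13 fell [8 and 15], asparagine synthetase (Asns) by 0.60 ± 0.044, and of the NF-kB targets 11 of 26 rose and 4 fell [11 and 4] (camera adjusted p = 0.0763 (0.0289 to 0.514) and 0.0763 (0.0411 to 0.467)). The first list passed downward with no filter on low counts (0.0361) and with a replicate block (0.0336) and without untreated replicate 1 (0.0289) or irradiated replicate 1 (0.0481), the second upward without irradiated replicate 1 (0.0411). Of the ERK-pathway outputs 4 of 24 rose and 10 fell [4 and 10] (camera adjusted p = 0.0871 (0.0296 to 0.616)), a list that passed downward without irradiated replicate 2 (0.0296). Mesenchymal (10 of 32 rose and 5 fell [10 and 5]), immediate-early (5 of 25 rose and 8 fell [5 and 8]) and NRF2 genes (9 of 26 rose and 9 fell [9 and 9]) had camera adjusted p = 0.236, 0.557 and 0.837. The immediate-early genes had a median of 0.019 and a mean of 0.090 while the test pointed down, and the homologous recombination and NRF2 lists also differed in sign between these measures.

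**Figure D3:**
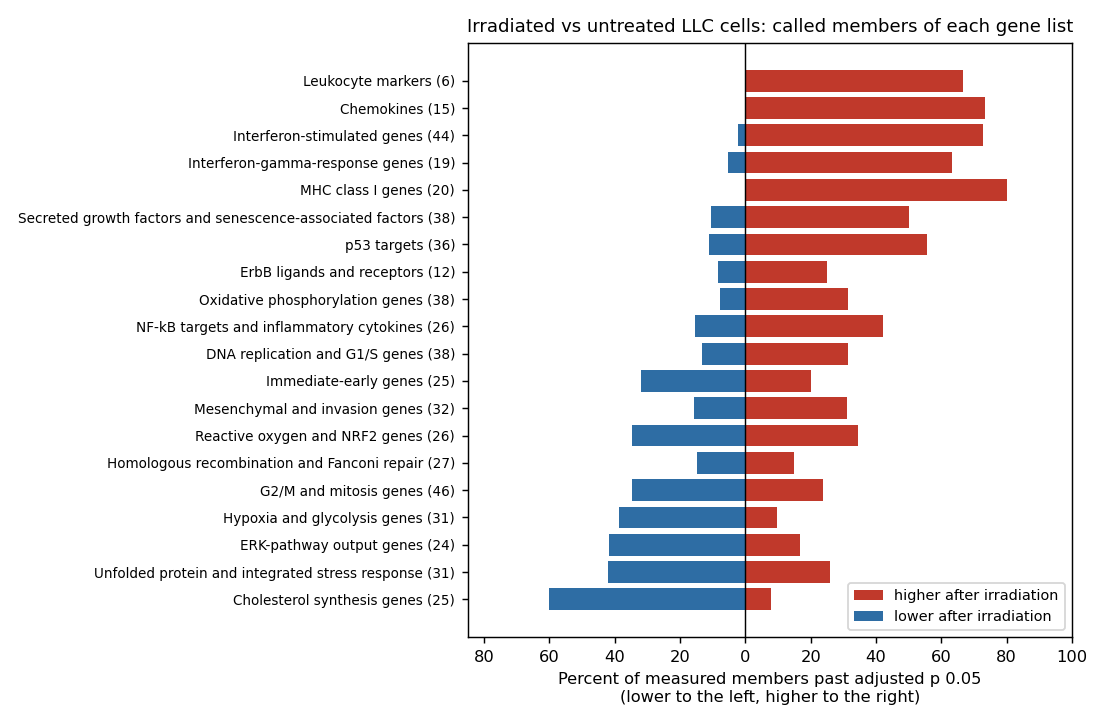
Percent of the measured members of each gene list (their number in brackets) past an edgeR adjusted p of 0.05 in irradiated against untreated LLC cells, higher to the right and lower to the left, in order of the list median. Of the cholesterol synthesis genes 15 of 25 are lower, and of the MHC class I genes 16 of 20 are higher.

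The next comparison asked what changes in EGFR+ MNPs when their tumour partner lacks AREG. With the AREG− partner, genes of the chemokine, NF-kB, interferon-gamma-response and NRF2 lists rose as groups, and genes of the ERK-pathway and hypoxia lists fell as groups, in camera with its preset correlation. With an estimated correlation the NRF2 list held (camera adjusted p = 0.0127) and the others did not (camera adjusted p = 0.258, 0.177, 0.318, 0.258 and 0.261 in the order named). The T-cell attractant Ccl17 rose from 28.7 ± 7.2 to 81.3 ± 7.3 CPM and the cytokine Il1a from 75.1 ± 6.4 to 167 ± 1.5 CPM (1.15 ± 0.073). The adhesion receptor Adgre4 rose from 30.1 ± 4.7 to 66.1 ± 12 CPM (1.13 ± 0.12) and the CXCR3 ligand Cxcl10 from 3.81 ± 0.21 to 8.27 ± 1.1 CPM (1.12 ± 0.15; edgeR adjusted p = 9.0e-08 to 3.3e-04 for these 4 genes). The metalloproteinase Mmp3 fell from 24.8 ± 8.9 to 2.62 ± 0.49 CPM (log2 fold change -3.25 ± 0.29, edgeR adjusted p = 1.5e-04). Tenm4, Col3a1, the IL-33 receptor Il1rl1, Dpysl3 and the mesenchymal factor Prrx1 fell by 2.13- to 4.52-fold (edgeR adjusted p = 1.5e-05 to 0.00543).

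In untreated LLC cells the transcripts of these 6 genes were more abundant than in the MNPs, at 237 CPM for Tenm4 to 3283 CPM for Col3a1. Of the 55 genes that fell by 2-fold or more, 40 (72.7%) were at least 10 times higher in LLC cells than in MNPs, against 6.03% of tested genes. Of 14700 genes tested, 864 rose and 742 fell with edgeR, 55 of each by 2-fold or more. Scaling by library size alone put 43.7% of called genes higher, against 53.8% here. The count of 1606 called genes was 731 and 942 without AREG+ replicate 1 or 3, and 919, 772 and 1029 without AREG− replicate 1, 2 or 3. That of 110 changes of 2-fold or more was 67 without AREG+ replicate 1, 21 with a filter of 5 CPM and 59 without LLC-dominant genes. With the length trend removed 1024 genes were called. Without the 3 libraries that stood apart as well, 73 changes were of 2-fold or more.

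Of the NF-kB targets 13 of 35 rose and 1 fell [16 and 1] (camera adjusted p = 2.5e-08 (9.0e-10 to 0.177)), with Il6 at 0.67 ± 0.12 and the adhesion molecule Icam1 at 0.43 ± 0.064 (edgeR adjusted p = 0.00245 and 6.5e-04). Of the chemokines 7 of 22 rose and 0 fell [8 and 0] (camera adjusted p = 8.8e-06 (7.4e-08 to 0.258)), including Ccl22 (from 1038 ± 184 to 1558 ± 75 CPM; edgeR adjusted p = 0.00111). Interferon-gamma-response genes (5 of 25 rose and 0 fell [7 and 0]) and pro-inflammatory genes (11 of 27 rose and 1 fell [12 and 1]) passed upward as well (camera adjusted p = 4.0e-04 (6.1e-06 to 0.318) and 4.0e-04 (1.0e-05 to 0.258)). The GTPase Gbp5 rose by 0.58 ± 0.082, the cytokine inhibitor Socs1 by 0.93 ± 0.15 and Cd40, a co-stimulatory receptor, by 0.65 ± 0.13, while Nos2 fell from 232 ± 13 to 136 ± 30.4 CPM (edgeR adjusted p = 4.9e-04 to 0.00745). Calls for interferon-stimulated genes (4 of 49 rose and 0 fell [3 and 0]) and immediate-early genes (6 of 25 rose and 1 fell [8 and 1]) were weaker (camera adjusted p = 0.0138 (2.8e-04 to 0.758) and 0.0144 (1.5e-04 to 0.289)). The first was lost without AREG+ replicate 3 (0.191), the second without AREG− replicate 2 (0.0855) or 3 (0.0585). The highest p of each range was that with an estimated correlation.

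Of the ERK-pathway outputs 1 of 25 rose and 8 fell [1 and 8], and of the hypoxia and glycolysis genes 0 of 31 rose and 6 fell [0 and 6] (camera adjusted p = 4.0e-04 (1.0e-05 to 0.258) and 1.9e-05 (1.1e-07 to 0.261)). Cyclin D1 (Ccnd1) fell from 60.6 ± 6.0 to 37.0 ± 3.4 CPM and LLC-dominant Etv1, possibly tumour RNA, from 6.08 ± 0.28 to 3.02 ± 0.61 CPM (edgeR adjusted p = 2.1e-04 and 8.1e-04). Vegfa fell from 232 ± 12 to 183 ± 19 CPM (edgeR adjusted p = 0.0131), but not without AREG+ replicate 3 (0.0546) or AREG− replicate 1 (0.0542), in a range of 0.00131 to 0.0546. Of the p53 targets 0 of 37 rose and 7 fell [1 and 10], among them Zmat3 and the DNA polymerase Polk, and of the stromal markers 1 of 13 rose and 4 fell [1 and 5], Col3a1 foremost (camera adjusted p = 0.0240 (0.0150 to 0.170) and 0.00977 (0.00182 to 0.170)). The p53 call was lost without AREG− replicate 3 (0.0585), the stromal one with no filter on low counts (0.0554). An estimated correlation gave each highest p.

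Of the NRF2 and reactive oxygen genes 11 of 26 rose and 0 fell [14 and 0], the 1 list here that held with an estimated correlation (camera adjusted p = 3.8e-08 (1.1e-09 to 0.0127), the highest being that p). Peroxiredoxin 1 (Prdx1) rose from 1400.3 ± 154 to 1923 ± 264 CPM and the mitochondrial superoxide dismutase Sod2 from 485 ± 9.8 to 642 ± 19 CPM (edgeR adjusted p = 0.00495 and 7.0e-04). Oxidative phosphorylation genes rose by a median of 0.20 (14 of 38 rose and 0 fell [29 and 0]). Camera gave this list an adjusted p of 1.6e-12 (3.0e-14 to 0.258), the highest with an estimated correlation. Its transcripts are short (median 1232 nucleotides), and the length trend and mitochondrial share differed between the same groups. With the length trend removed, the list median was 0.087 and 4 members passed in place of 14. DNA replication genes (8 of 38 rose and 0 fell [8 and 0]) and stress-response genes (7 of 31 rose and 1 fell [13 and 3]) passed upward (camera adjusted p = 2.2e-04 (5.0e-05 to 0.170) and 0.00996 (0.00473 to 0.258), the highest with an estimated correlation).

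Phagocyte genes moved in both directions. The beta-glucan receptor Clec7a rose from 127 ± 8.3 to 252 ± 39 CPM and the scavenger receptor Marco from 449 ± 109 to 666 ± 36 CPM (edgeR adjusted p = 2.0e-05 and 0.0133). The mannose receptor Mrc1 fell from 170.2 ± 29 to 100.6 ± 6.0 CPM (edgeR adjusted p = 4.9e-04). The phagocytosis (5 of 45 rose and 6 fell [5 and 6]), immunosuppressive (5 of 44 rose and 8 fell [6 and 9]) and macrophage lists (4 of 32 rose and 3 fell [5 and 3]) did not pass (camera adjusted p = 0.775, 0.720 and 0.260). Classical monocyte genes (10 of 29 rose and 2 fell [12 and 2]) and lipid and lysosome genes (12 of 38 rose and 2 fell [13 and 2]) passed upward (camera adjusted p = 7.8e-04 (4.3e-05 to 0.258) and 6.0e-04 (2.4e-05 to 0.272), the highest with an estimated correlation). The proton pump subunit Atp6v0d2 rose by 0.75 ± 0.092 (edgeR adjusted p = 1.7e-04).

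The sorting antigen gene Ly6c2 rose by 0.21 ± 0.065 (edgeR adjusted p = 0.0415), but not without AREG+ replicate 2 (0.126) or 3 (0.118) or AREG− replicate 1 (0.132), 2 (0.0605) or 3 (0.0541), in a range of 0.0123 to 0.132. Csf1r, Sirpa, Cd274, Il10, Mertk, Hbegf, Ereg, Egfr and Arg1 did not pass (edgeR adjusted p = 0.0690 to 0.993). Arg1 fell past the threshold with a replicate block (0.0394) and without AREG+ replicate 1 (0.00557) or AREG− replicate 3 (0.0421), in a range of 0.00557 to 0.222. Egfr did so in DESeq2 (0.0422) and without AREG+ replicate 2 (0.04997), in a range of 0.0422 to 0.277, and Ereg without AREG+ replicate 2 (0.0245), in a range of 0.0245 to 0.494.

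Among markers of other cell types, those of dendritic cells (3 of 19 rose and 1 fell [5 and 1]) and of mast cells, basophils and eosinophils (6 of 20 rose and 1 fell [6 and 1]) passed upward (camera adjusted p = 0.00977 (0.00194 to 0.289) and 0.0138 (9.1e-04 to 0.416)), the second not without AREG+ replicate 2 (0.0740). MHC class I (3 of 20 rose and 0 fell [7 and 0]) and class II genes (0 of 11 rose and 0 fell [0 and 0]) passed upward too (camera adjusted p = 0.0138 (6.3e-04 to 0.459) and 0.0387 (0.00256 to 0.814, and 0.656 with an estimated correlation)). The class I call was lost without AREG+ replicate 1 (0.0736), the class II call without AREG+ replicate 1 (0.814) or AREG− replicate 1 (0.0819) or 3 (0.0585). Where no other p is named, the highest is that with an estimated correlation. Neutrophil markers (1 of 21 rose and 2 fell [3 and 3]) did not pass, nor did LLC, lymphocyte, erythroid and myeloid progenitor markers (camera adjusted p = 0.942, 0.745, 0.928, 0.684 and 0.173). The ErbB, homologous recombination, G2/M and cholesterol lists did not pass either (camera adjusted p = 0.720, 0.811, 0.392 and 0.357). Neutrophil markers passed upward without AREG+ replicate 1 (0.00174), in a range of 0.00174 to 0.982, and G2/M genes without AREG+ replicate 1 (0.0270), in a range of 0.0270 to 0.960.

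The same change of tumour partner was then examined in EGFR− MNPs, in which many of the genes named above moved in the same direction. Il1a rose from 73.2 ± 4.6 to 159 ± 11 CPM (1.12 ± 0.073) and Cxcl10 from 2.63 ± 0.69 to 6.92 ± 0.55 CPM (1.39 ± 0.15). Adgre4 rose by 1.15 ± 0.12 and Ccl17 by 1.12 ± 0.14 (edgeR adjusted p = 1.5e-07 to 7.6e-04 for the 4 genes). Mmp3 fell from 26.0 ± 5.2 to 2.27 ± 0.44 CPM (-3.52 ± 0.29), Col3a1 by 1.98 ± 0.25 and Il1rl1 by 1.35 ± 0.18 (edgeR adjusted p = 7.5e-05 to 0.00128). In all, 273 genes rose and 223 fell with edgeR, 35 and 41 of them by 2-fold or more. Of these 41 falls, 24 (58.5%) were in genes at least 10 times higher in LLC cells than in MNPs. The count of 496 was 234 without AREG+ replicate 1 and 274, 246 and 300 without AREG− replicate 1, 2 or 3. It was 786 in DESeq2, 1217 without the 3 libraries that stood apart and 1313 with the length trend removed as well. The 76 changes of 2-fold or more were 20 with a filter of 5 CPM and 48 without LLC-dominant genes.

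Of the interferon-stimulated genes 23 of 49 rose and 0 fell [38 and 0], and of the interferon-gamma-response genes 9 of 25 rose and 0 fell [16 and 0] (camera adjusted p = 1.4e-38 (6.6e-60 to 0.0547) and 7.4e-18 (1.4e-20 to 0.0362)). Ifit3b, whose reads may be shared with Ifit3, rose from 5.06 ± 1.5 to 9.36 ± 0.93 CPM, Gbp5 by 0.56 ± 0.081 and Socs1 by 1.05 ± 0.15 (edgeR adjusted p = 7.4e-04 to 0.00334). Of the NF-kB targets 15 of 35 rose and 0 fell [22 and 0] and of the chemokines 5 of 22 rose and 0 fell [10 and 0] (camera adjusted p = 1.2e-23 (1.5e-25 to 0.0108) and 4.0e-08 (1.6e-09 to 0.104)). Pro-inflammatory genes (9 of 27 rose and 1 fell [11 and 1]) and immediate-early genes (2 of 25 rose and 0 fell [8 and 1]) passed upward (camera adjusted p = 1.0e-05 (8.7e-07 to 0.104) and 2.7e-05 (2.6e-06 to 0.0362)). The highest p of each range is that with an estimated correlation, under which the interferon-gamma-response, NF-kB and immediate-early calls held.

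ERK-pathway outputs (1 of 25 rose and 7 fell [2 and 8]), hypoxia genes (0 of 31 rose and 7 fell [0 and 19]) and p53 targets (0 of 37 rose and 7 fell [0 and 7]) passed downward (camera adjusted p = 6.6e-04 (1.8e-04 to 0.156), 5.8e-13 (1.6e-14 to 0.0373) and 2.9e-04 (1.1e-04 to 0.0157)). Ccnd1 fell by 0.78 ± 0.091, LLC-dominant Etv1 by 0.92 ± 0.15 and Vegfa from 215 ± 7.2 to 159 ± 14 CPM (edgeR adjusted p = 8.3e-05 to 0.00396). Mrc1 fell from 138 ± 13 to 72.0 ± 7.3 CPM and Nos2 by 0.71 ± 0.11, while Clec7a rose by 0.76 ± 0.095 (edgeR adjusted p = 8.3e-05 to 0.00161). Classical monocyte (9 of 29 rose and 1 fell [13 and 1]), NRF2 (4 of 26 rose and 0 fell [8 and 0]) and myeloid progenitor genes (4 of 15 rose and 1 fell [8 and 1]) passed upward (camera adjusted p = 8.5e-07 (4.1e-07 to 0.0108), 1.1e-06 (1.9e-07 to 0.0157) and 3.9e-04 (1.4e-04 to 0.0260)). All these lists but the ERK outputs held with an estimated correlation, which gave each highest p.

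Mast cell, basophil and eosinophil markers (6 of 20 rose and 0 fell [9 and 0]), MHC class I genes (1 of 20 rose and 0 fell [1 and 0]), lipid genes (5 of 38 rose and 0 fell [10 and 2]) and erythroid markers (1 of 11 rose and 0 fell [2 and 0]) passed upward. These had, in that order, camera adjusted p = 4.3e-09 (1.8e-10 to 0.0547), 5.3e-07 (2.3e-09 to 0.104), 0.00122 (4.9e-04 to 0.223) and 0.00991 (6.5e-04 to 0.104). Other upward calls, for oxidative phosphorylation (0 of 38 rose and 0 fell [0 and 0]), stress-response (0 of 31 rose and 1 fell [4 and 2]), MHC class II (0 of 11 rose and 0 fell [0 and 0]) and dendritic cell lists (3 of 19 rose and 0 fell [4 and 2]), rested on single libraries. These had camera adjusted p = 8.8e-04 (4.7e-06 to 0.456), 0.0113 (0.00145 to 0.181), 0.00584 (0.00152 to 0.422) and 0.0486 (0.0210 to 0.410). They were lost, in that order, without AREG+ replicate 3 (0.328), without AREG+ replicate 3 (0.121) or AREG− replicate 2 (0.0650), without AREG+ replicate 3 (0.0842) and with DESeq2-type size factors (0.0599) and without AREG+ replicate 2 (0.0529) or 3 (0.125) or AREG− replicate 3 (0.165). Homologous recombination (0 of 27 rose and 0 fell [0 and 0]) and cholesterol genes (0 of 25 rose and 0 fell [0 and 0]) passed downward (camera adjusted p = 0.00584 (0.00186 to 0.104) and 0.00952 (0.00267 to 0.181)), the first not without AREG+ replicate 3 (0.0536) and the second not without AREG+ replicate 2 (0.0506) or AREG− replicate 1 (0.0511). The highest p of each range is that with an estimated correlation. The other 10 lists had camera adjusted p from 0.110 for stromal to 0.822 for lymphocyte markers.

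Of the panel, Arg1 fell from 807 ± 85 to 483 ± 54 CPM (edgeR adjusted p = 0.0125), a call lost with no filter on low counts (0.0764) and without replicate 1 of the AREG+ (0.0554) or AREG− group (0.0560), in a range of 0.00240 to 0.0764. Ly6c2 rose by 0.25 ± 0.065 (edgeR adjusted p = 0.0348), but not without AREG+ replicate 1 (0.174) or 3 (0.0610) or AREG− replicate 1 (0.115), 2 (0.0822) or 3 (0.130), in a range of 0.00211 to 0.174. Egfr fell by 0.68 ± 0.18 (edgeR adjusted p = 0.0485), but not in limma-voom (0.0852), with DESeq2-type size factors (0.0523) or without AREG+ replicate 1 (0.0638), 2 (0.0932) or 3 (0.171) or AREG− replicate 1 (0.0918), 2 (0.183) or 3 (0.170), in a range of 0.0150 to 0.183. Csf1r and Cd274 did not pass (edgeR adjusted p = 0.180 and 0.102). Csf1r rose past the threshold without AREG+ replicate 3 (0.0180) and Cd274 in DESeq2 (0.0179), in ranges of 0.0180 to 0.525 and 0.0179 to 0.373.

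**Figure D4:**
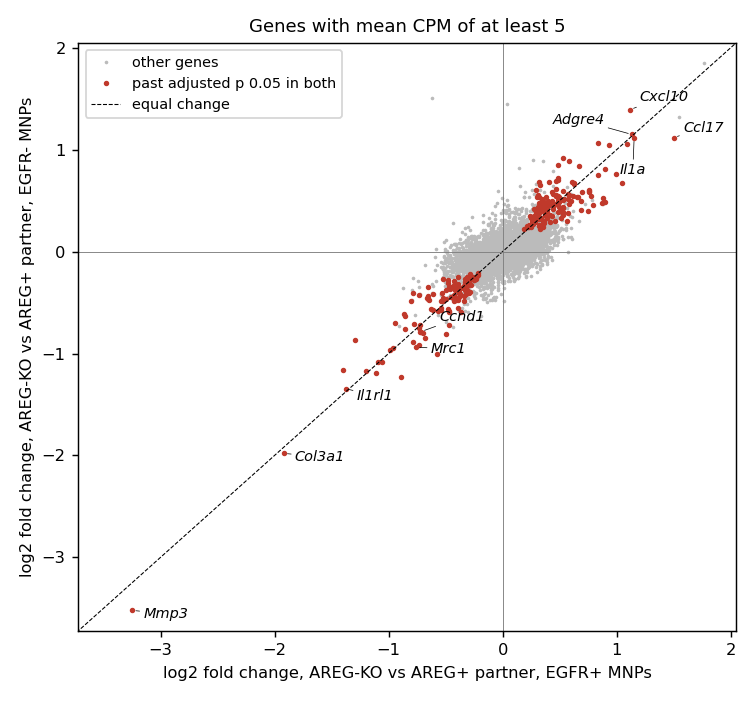
Log2 fold change with the AREG− against the AREG+ partner in EGFR+ MNPs (horizontal) and EGFR− MNPs (vertical), with 1 point per gene of at least 5 CPM, genes past the threshold in both in red and a dashed line of equal change. Il1a lies at 1.15 and 1.12 and Mmp3 at -3.25 and -3.52.

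These responses to the AREG− partner share no library. Of their called genes 189 rose in both, against 16.05 for independent lists, 145 fell in both, against 11.3, and 0 moved in opposite directions. The fold changes correlated with r = 0.43 across all tested genes and r = 0.67 across the 9752 of at least 5 CPM, but with r = 0.12 with no filter on low counts. Over genes of at least 5 CPM r was 0.445 without EGFR−/AREG+ replicate 3. The shared rises and falls were 109 and 87 without EGFR−/AREG+ replicate 1, and 135 and 91, 109 and 77, and 121 and 85 without EGFR−/AREG− replicate 1, 2 or 3. Without the 3 libraries that stood apart they were 326 and 206, with 31 genes in opposite directions (330, 217 and 7 with the length trend removed as well), and without EGFR−/AREG+ replicate 3 alone 4 genes were opposite. Genes are not independent replicates.

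The receptor comparison set EGFR− against EGFR+ MNPs, both with the AREG+ partner. MHC class II genes, dendritic cell markers and co-stimulatory genes were higher as groups in EGFR− MNPs, and neutrophil markers and immediate-early genes were lower, in camera with its preset correlation. None held with an estimated correlation (camera adjusted p = 0.289, 0.261, 0.387, 0.324 and 0.289 in that order). The neutrophil markers S100a9 and S100a8 stood at means of 10581 and 7339 CPM over the MNP libraries. A change in the mix of sorted cells was not separated from a change within cells. After Lyz2, the largest fall was that of Lyz1, whose reads may be shared with Lyz2 (from 39.9 ± 11 to 7.35 ± 0.75 CPM, edgeR adjusted p = 0.00923). It was not called without EGFR− replicate 1 (0.0543, in a range of 2.3e-07 to 0.0543). The endosomal gene Wdfy1 fell from 49.3 ± 1.7 to 17.6 ± 1.1 CPM (-1.48 ± 0.063) and the metalloreductase Steap4 from 20.5 ± 3.6 to 7.97 ± 0.39 CPM (-1.36 ± 0.11). The syntenin gene Sdcbp2 rose from 2.66 ± 0.56 to 7.87 ± 0.76 CPM (1.57 ± 0.14; edgeR adjusted p = 6.2e-11 to 3.0e-06 for these 3 genes).

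Here 997 genes rose and 723 fell of 14700 tested with edgeR, 55 and 17 of them by 2-fold or more. With scaling by library size alone, 74.7% of called genes were higher, against 58.0% here. Without EGFR+ replicate 1 the count of 1720 was 453, and without EGFR− replicate 1, 2 or 3 it was 513, 633 or 3400. It was 657 with only the compared groups in the fit, 3731 without the 3 libraries that stood apart and 2640 with the length trend removed as well. The 72 changes of 2-fold or more were 13 with a filter of 5 CPM, 32 without EGFR+ replicate 1, and 42 and 47 without EGFR− replicate 1 and 2.

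Of the MHC class II genes 10 of 11 rose and 0 fell [10 and 0], and of the dendritic cell markers 9 of 19 rose and 0 fell [10 and 0] (camera adjusted p = 1.3e-09 (6.0e-11 to 0.289) and 9.9e-08 (1.0e-08 to 0.261)). The master regulator Ciita rose from 23.4 ± 3.4 to 38.9 ± 3.1 CPM, H2-Aa from 306 ± 56 to 474 ± 29.7 CPM and the migration receptor Ccr7 from 382 ± 62 to 655 ± 22 CPM (edgeR adjusted p = 4.4e-05 to 8.2e-04). The lectin Mgl2 rose by 1.12 ± 0.11 and Ccl17 by 1.09 ± 0.15 (edgeR adjusted p = 1.4e-05 and 5.4e-04). Of the pro-inflammatory and co-stimulatory genes 9 of 27 rose and 2 fell [11 and 4], with Cd86 from 48.7 ± 7.1 to 91.4 ± 9.6 CPM (edgeR adjusted p = 4.0e-05). MHC class I (7 of 20 rose and 0 fell [8 and 0]), lipid (9 of 38 rose and 0 fell [11 and 0]) and NRF2 genes (8 of 26 rose and 2 fell [12 and 2]) also passed upward. These 4 lists had camera adjusted p = 0.00336 (1.6e-04 to 0.387), 0.00169 (5.6e-05 to 0.409), 5.2e-04 (3.0e-05 to 0.324) and 0.00544 (0.00202 to 0.261). Each range ended with the p under an estimated correlation.

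Of the neutrophil markers 1 of 21 rose and 13 fell [1 and 13] (camera adjusted p = 4.8e-08 (1.1e-10 to 0.324)), among them Retnlg from 239 ± 45 to 129 ± 5.6 CPM and the chemokine receptor Cxcr2 from 491 ± 92 to 285 ± 24 CPM (edgeR adjusted p = 9.0e-05 and 1.3e-04). Immediate-early genes (2 of 25 rose and 9 fell [3 and 13]), ERK outputs (0 of 25 rose and 4 fell [1 and 5]) and G2/M genes (0 of 46 rose and 7 fell [0 and 9]) passed downward (camera adjusted p = 9.5e-05 (9.3e-06 to 0.289), 0.00240 (8.6e-05 to 0.324) and 8.6e-05 (6.3e-06 to 0.324)). Classical monocyte (3 of 29 rose and 6 fell [3 and 8]) and interferon-stimulated genes (0 of 49 rose and 9 fell [0 and 9]) passed downward too (camera adjusted p = 0.0320 (0.0155 to 0.409) and 0.00910 (1.5e-11 to 0.860)), the first, which holds Lyz2, not without EGFR+ replicate 3 (0.0747) or EGFR− replicate 3 (0.0884) and the second not without EGFR+ replicate 2 (0.293) or EGFR− replicate 1 (0.763) or 3 (0.110). The highest p of each range was that with an estimated correlation.

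Of the interferon-gamma-response genes 8 of 25 rose and 1 fell [8 and 2], of the oxidative phosphorylation genes 10 of 38 rose and 0 fell [27 and 0] and of the DNA replication genes 5 of 38 rose and 2 fell [8 and 2], all passing upward (camera adjusted p = 0.00317 (5.7e-05 to 0.539), 5.5e-10 (1.0e-11 to 0.324) and 0.00544 (0.00205 to 0.324), the highest with an estimated correlation). The first call was lost without EGFR− replicate 2 (0.0573). Gbp5 rose by 0.61 ± 0.082 (edgeR adjusted p = 2.6e-04). The oxidative phosphorylation genes, at a median of 0.20, again moved with the length trend and the mitochondrial share. With the length trend removed their median was 0.066 and 3 members passed in place of 10. Of the fixed panel, which does not hold Lyz1, Lyz2 alone passed (edgeR adjusted p of the others 0.0925 for Areg to 0.947 for Ly6c2). Ereg fell past the threshold without EGFR+ replicate 2 (0.0247) and Sirpa without EGFR− replicate 3 (0.0205), in ranges of 0.0247 to 0.559 and 0.0205 to 0.550.

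The other 17 lists had camera adjusted p from 0.113 for mast cell to 0.936 for macrophage genes. Mast cell, basophil and eosinophil markers passed upward without EGFR+ replicate 1 (0.00682) or EGFR− replicate 1 (0.0295), cholesterol genes, upward, without EGFR+ replicate 1 (0.0307) and LLC markers, downward, without EGFR+ replicate 2 (0.00122), in ranges of 0.00682 to 0.682, 0.0307 to 0.636 and 0.00122 to 0.951. Median, mean and test differed in sign for the NF-kB list (median -0.038, mean 0.021, test down) and for the ErbB, p53, chemokine, immunosuppressive, macrophage and erythroid lists.

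With the AREG− partner, MHC class II genes, dendritic cell markers and interferon-gamma-response genes were again higher and neutrophil markers lower in EGFR− than in EGFR+ MNPs, in camera with its preset correlation. None held with an estimated correlation (camera adjusted p = 0.195 to 0.251), and cell mix was again not separated. Ciita rose from 22.5 ± 0.93 to 44.2 ± 3.8 CPM (0.97 ± 0.10) and Tex14 by 1.38 ± 0.12 (edgeR adjusted p = 1.3e-05 and 2.5e-06). Wdfy1 fell by 1.52 ± 0.064 and Steap4 from 22.96 ± 2.6 to 9.68 ± 0.71 CPM (edgeR adjusted p = 4.7e-11 and 6.0e-06). In all, 388 genes rose and 210 fell with edgeR, 32 and 14 by 2-fold or more. Scaling by library size alone put 78.0% higher, against 64.9% here. The count of 598 was 303 and 358 without EGFR+ replicate 2 or 3, and 302, 360 and 368 without EGFR− replicate 1, 2 or 3. It was 964 in DESeq2, 936 with only the compared groups in the fit, 2334 without the 3 libraries that stood apart and 2495 with the length trend removed as well. The 46 changes of 2-fold or more were 10 with a filter of 5 CPM, and 81 and 84 in the last 2 settings.

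MHC class II (8 of 11 rose and 0 fell [10 and 0]), dendritic cell (8 of 19 rose and 0 fell [9 and 0]), MHC class I (6 of 20 rose and 0 fell [11 and 0]) and co-stimulatory genes (9 of 27 rose and 0 fell [11 and 1]) passed upward (camera adjusted p = 3.0e-13 (3.9e-14 to 0.195), 1.4e-08 (1.9e-09 to 0.195), 6.0e-08 (9.1e-09 to 0.228) and 3.2e-05 (4.1e-06 to 0.234)). H2-Aa rose from 348 ± 18 to 526 ± 28 CPM, Ccr7 from 428 ± 7.9 to 685 ± 8.6 CPM and Cd40 by 0.69 ± 0.13 (edgeR adjusted p = 1.8e-04 to 0.00608). Interferon-gamma-response (8 of 25 rose and 0 fell [13 and 0]) and interferon-stimulated genes (9 of 49 rose and 0 fell [20 and 1]) passed upward (camera adjusted p = 5.0e-13 (1.4e-13 to 0.195) and 4.3e-10 (3.2e-11 to 0.385)). Mast cell, basophil and eosinophil markers (5 of 20 rose and 1 fell [7 and 1]) and lipid genes (3 of 38 rose and 0 fell [6 and 0]) did so too (camera adjusted p = 1.1e-04 (1.9e-05 to 0.295) and 0.00198 (2.7e-04 to 0.372)). The upper end of each range is the p with an estimated correlation.

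Neutrophil markers (0 of 21 rose and 7 fell [0 and 13]), immediate-early genes (1 of 25 rose and 3 fell [2 and 10]) and G2/M genes (0 of 46 rose and 1 fell [0 and 1]) passed downward (camera adjusted p = 1.2e-10 (5.9e-12 to 0.251), 2.4e-05 (1.0e-07 to 0.196) and 1.1e-07 (2.9e-09 to 0.228)). Retnlg fell from 218 ± 23 to 106 ± 8.7 CPM and Cxcr2 by 0.63 ± 0.10 (edgeR adjusted p = 2.3e-05 and 0.00103). Weaker calls were downward for ERK outputs (0 of 25 rose and 2 fell [1 and 7]), DNA replication (0 of 38 rose and 0 fell [0 and 0]) and hypoxia genes (0 of 31 rose and 1 fell [0 and 0]) and upward for NF-kB targets (5 of 35 rose and 0 fell [7 and 2]). These had camera adjusted p = 0.0123 (7.8e-04 to 0.372), 0.0349 (0.00866 to 0.349), 0.0489 (0.00110 to 0.611, and 0.591 with an estimated correlation) and 0.0350 (0.0154 to 0.526). They were lost, in that order, without EGFR+ replicate 3 (0.117), without EGFR+ replicate 2 (0.05004) or EGFR− replicate 2 (0.121), with no filter on low counts (0.0510) and without EGFR+ replicate 3 (0.611) or EGFR− replicate 1 (0.181) or 2 (0.0927) and with a replicate block (0.0545) and without EGFR+ replicate 1 (0.154) or EGFR− replicate 2 (0.127). Where no other p is named, the upper end is that with an estimated correlation.

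The other 17 lists had camera adjusted p from 0.0519 for oxidative phosphorylation to 0.917 for phagocytosis genes. Oxidative phosphorylation genes passed upward with no filter on low counts (0.0226) and without EGFR+ replicate 1 (3.4e-04) or EGFR− replicate 1 (0.00559), classical monocyte genes, downward, without EGFR+ replicate 2 (0.0193) or 3 (0.0230) and homologous recombination genes, downward, without EGFR+ replicate 3 (0.0221), in ranges of 3.4e-04 to 0.748, 0.0193 to 0.801 and 0.0221 to 0.753. Classical monocyte genes had a median of 0.024, a mean of -0.32 and a test pointing down, and the chemokine, stress-response, phagocytosis and progenitor lists also differed in sign between these measures. Lyz1 fell from 59.3 ± 37 to 7.35 ± 0.42 CPM (-3.01 ± 0.42; edgeR adjusted p = 0.00566). Of the fixed panel Lyz2 alone passed (edgeR adjusted p of the others 0.0536 for Cd274 to 0.906 for Il10). Cd274 was called in DESeq2 (0.00834), limma-voom (0.0497), with no filter on low counts (0.0435) and without EGFR+ replicate 1 (0.0419), as was Vegfa without that library (0.0450), in ranges of 0.00834 to 0.198 and 0.0450 to 0.528. With either partner 270 genes rose and 150 fell in EGFR− MNPs, against 26.3 and 10.3 for independent lists, and 0 moved in opposite directions. The fold changes correlated with r = 0.38 across tested genes, r = 0.74 across those of at least 5 CPM and r = 0.0484 with no filter. The shared rises and falls were 171 and 65 or 183 and 86 without EGFR+/AREG− replicate 2 or 3, 196 and 86 without EGFR−/AREG+ replicate 1, and 187 and 61, 187 and 84, and 190 and 72 without EGFR−/AREG− replicate 1, 2 or 3. Without the 3 libraries that stood apart they were 617 and 752, with 38 opposite (514, 801 and 11 with the length trend removed as well). Without EGFR−/AREG+ replicate 3 alone 13 were opposite.

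**Figure D5:**
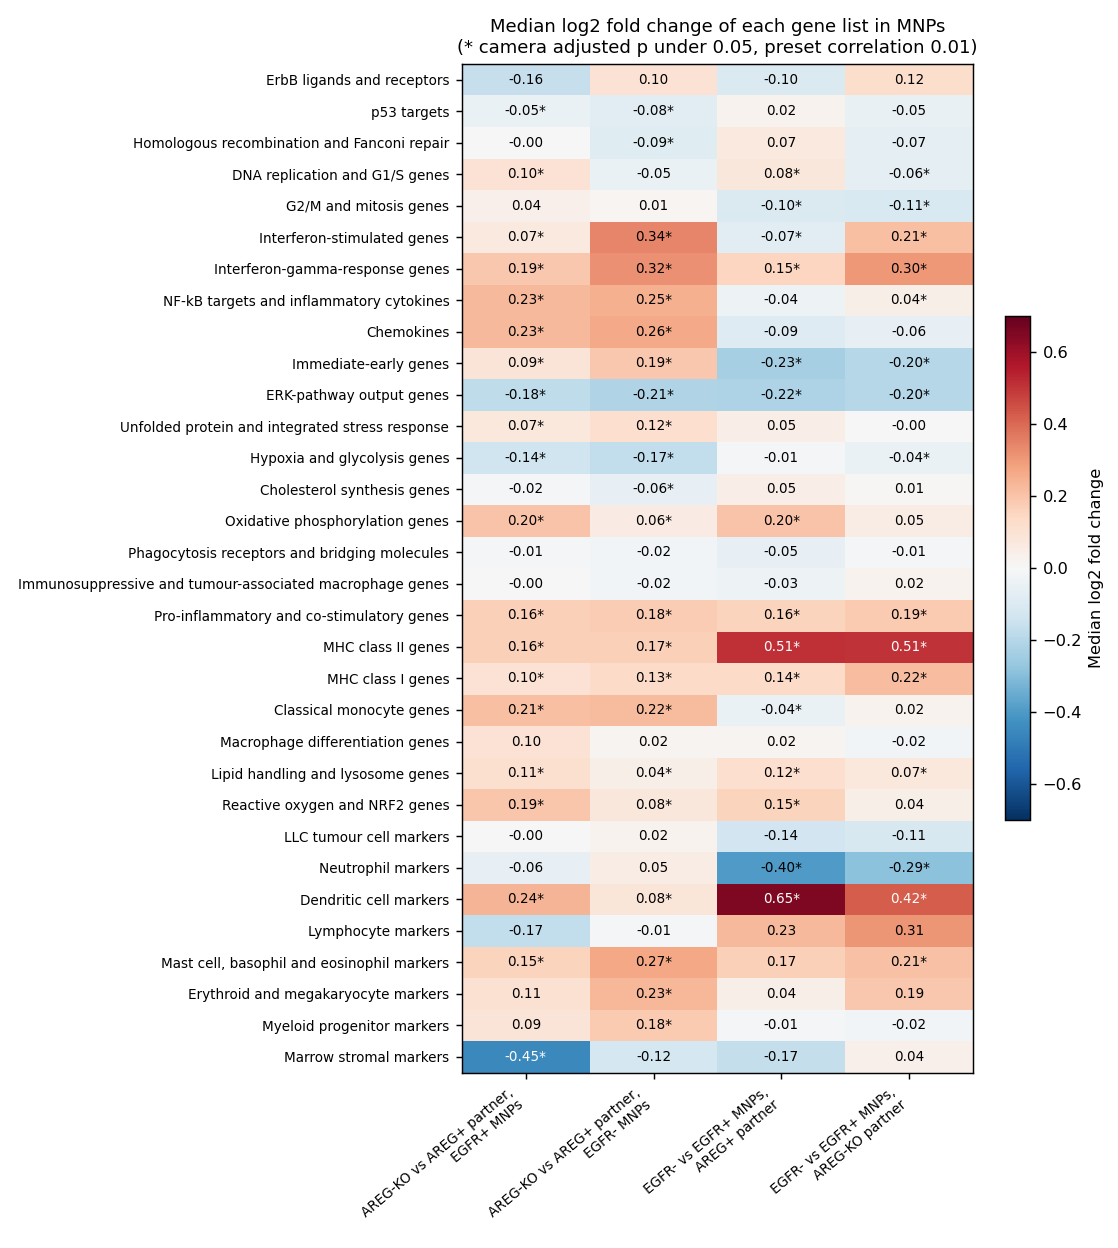
Median log2 fold change of each of the 32 gene lists (vertical) in the 4 MNP comparisons (horizontal), as a colour scale with the value in each cell and an asterisk where camera's adjusted p is under 0.05. MHC class II genes stand at 0.51 in both genotype comparisons, and interferon-stimulated genes at 0.34 with the AREG− partner in EGFR− MNPs against 0.070 in EGFR+ MNPs.

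The interaction tested whether the response to the AREG− partner depends on the MNP genotype. The fold changes of Arg1, Nos2 and Vegfa differed between the genotypes by -0.30 ± 0.21, 0.062 ± 0.16 and -0.091 ± 0.11, none past the threshold (edgeR adjusted p = 0.767, 0.944 and 0.870). In edgeR 0 genes passed, with 995 at an unadjusted p under 0.05 where chance gives 735 and a smallest adjusted p of 0.722. DESeq2, limma-voom and limma-trend also called 0 genes (1092, 1039 and 1046 at that unadjusted p). Without EGFR−/AREG+ replicate 3, which stood apart, edgeR called 151 genes, and 1 gene without EGFR−/AREG− replicate 3. Without all 3 libraries that stood apart it called 427 genes (5 of 2-fold or more), and 40 (1 of 2-fold or more) with the length trend removed as well. In simulated data 62% of 2-fold interaction effects were recovered.

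As groups, interferon-stimulated genes responded more in EGFR− than in EGFR+ MNPs (median difference 0.29), and DNA replication and oxidative phosphorylation genes less (-0.16 and -0.16; camera adjusted p = 1.7e-22 (5.1e-59 to 0.564), 4.7e-08 (2.6e-09 to 0.0818) and 2.9e-08 (1.8e-10 to 0.614)). Upward calls were also made for interferon-gamma-response genes (0.12) and NF-kB targets (0.055), and a downward call for NRF2 genes (-0.094; camera adjusted p = 0.00202 (8.7e-08 to 0.763), 0.0423 (4.8e-05 to 0.763) and 0.0423 (0.00872 to 0.485)). In each range the highest p is that with an estimated correlation, under which none of the 6 calls held. The interferon-gamma call was lost without EGFR+/AREG+ replicate 2 (0.136) or EGFR−/AREG+ replicate 3 (0.124). The NF-kB call was lost without EGFR+/AREG+ replicate 2 (0.281) or EGFR+/AREG− replicate 1 (0.156) or EGFR−/AREG+ replicate 1 (0.325) or 3 (0.206) or EGFR−/AREG− replicate 2 (0.130) or 3 (0.0534). The NRF2 call was lost with DESeq2-type size factors (0.0605) and without EGFR+/AREG+ replicate 3 (0.154) or EGFR+/AREG− replicate 1 (0.0591) or 2 (0.144) or EGFR−/AREG+ replicate 1 (0.0504), 2 (0.0830) or 3 (0.0670) or EGFR−/AREG− replicate 2 (0.0727) or 3 (0.0944). The oxidative phosphorylation genes moved with the length trend. Removing it ended their call (camera adjusted p = 0.143), as the median difference went from -0.16 ± 0.0757 to -0.026 ± 0.0236 (SE between libraries).

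The other 26 lists did not pass (camera adjusted p = 0.0558 for mast cell to 0.976 for MHC class II genes). Mast cell, basophil and eosinophil markers passed upward without EGFR+/AREG+ replicate 2 (0.0171) or 3 (0.0305) or EGFR+/AREG− replicate 1 (0.0361) or 3 (0.0290) or EGFR−/AREG+ replicate 2 (5.0e-04) or EGFR−/AREG− replicate 1 (0.0117). Neutrophil markers passed in opposite directions, downward without EGFR+/AREG+ replicate 1 (median -0.14; 0.00387) and upward without replicate 3 of that group (0.095; 0.0407). MHC class II genes, whose test pointed down with all libraries, passed upward without EGFR+/AREG+ replicate 1 (0.0107) with a median of 0.10. MHC class I genes passed upward without EGFR+/AREG+ replicate 1 (0.0141) or EGFR−/AREG+ replicate 2 (0.00770). Homologous recombination genes passed downward without EGFR+/AREG− replicate 3 (0.0250) or EGFR−/AREG+ replicate 2 (0.00976) and hypoxia genes without EGFR+/AREG− replicate 1 (0.00583). The lipid list passed downward and the LLC list upward without EGFR+/AREG+ replicate 2 (0.0188) in each case. The ranges of these 8 lists were, in the order named, 5.0e-04 to 0.763, 0.00387 to 0.967, 0.0107 to 0.994, 0.00770 to 0.998, 0.00976 to 0.763, 0.00583 to 0.966, 0.0188 to 0.790 and 0.0188 to 0.967.

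The AREG− partner and the EGFR− genotype were finally compared, each against EGFR+ MNPs with the AREG+ partner. Ccl17, Ccl22, Cd40, Gbp5 and Atp6v0d2 rose in both. Both comparisons called 245 genes higher and 156 lower, against 58.6 and 36.5 for independent lists, and 17 in opposite directions. Without EGFR+/AREG+ replicate 1 the comparisons called 731 and 453 genes in place of 1606 and 1720. They shared 35 rises and 16 falls, against 7.38 and 3.94, with 18 opposite. The shared rises and falls were 148 and 113 without replicate 3 of that group, 131 and 92, 118 and 78, and 144 and 96 without EGFR+/AREG− replicate 1, 2 or 3, and 62 and 33, 70 and 55, and 562 and 694 without EGFR−/AREG+ replicate 1, 2 or 3. The shared controls also had the highest length trend (0.25, against -0.093 and -0.045 in the compared groups). With that trend removed 155 rises and 98 falls were shared, against 30.04 and 25.1, with 26 opposite. Without the 3 libraries that stood apart these were 336 and 543, with 118 opposite (169, 186 and 128 with the trend removed as well). Their fold changes correlated with r = 0.43 and a covariance of 0.0682. Unchanged groups simulated 20 times against 3 shared controls gave r = 0.502, a covariance of 0.0333 and 0 shared calls, the last nearly by construction. The covariance exceeded the simulated one by 0.0349, and by 0.0156 over genes of at least 5 CPM (0.0200 against 0.00436). Over the latter genes the covariance was 0.0125 without EGFR+/AREG+ replicate 1, 0.0119 with the length trend removed, and 0.00544 with that and without the 3 libraries that stood apart. Part of the excess in covariance and over independent lists may come from the 3 shared controls, as no split leaves 2 on each side.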

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

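Tests of reads from the MNP libraries, of all 3 kinds of tumour RNA, of the length trend as a whole cause and of the partner effect carried by interaction splits were chosen after the results were seen. The length explanation itself was raised by the names of the 151 genes, but its bounds were set before corrected values were computed, with 1 form of the correction tried.

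Camera called 6 lists in the interaction, a difference between the genotypes in the response to the AREG− partner. Median differences (EGFR− minus EGFR+ MNPs, log2) were -0.16 for DNA replication, 0.29 for interferon-stimulated, 0.12 for interferon-gamma-response, 0.055 for NF-kB, -0.16 for oxidative phosphorylation and -0.094 for NRF2 genes. None held with an estimated correlation (adjusted p = 0.0818, 0.564, 0.763, 0.763, 0.614 and 0.485 in that order, the highest of the ranges 2.6e-09 to 0.0818, 5.1e-59 to 0.564, 8.7e-08 to 0.763, 4.8e-05 to 0.763, 1.8e-10 to 0.614 and 0.00872 to 0.485). With the length trend removed the call for oxidative phosphorylation genes was lost (median -0.026; camera adjusted p = 0.143). Single libraries behind the interferon-gamma-response, NF-kB and NRF2 calls are named with the interaction.

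The first pattern was the rise of low-abundance genes in irradiated LLC cells, with a median of 0.27 (log2) in 2123 genes under 1 CPM. Reads spilled over from the MNP libraries are argued against: 50 genes abundant in MNPs reached a median of 0.00147% of their MNP level in the irradiated libraries, and 5 genes above 1000 CPM in MNPs had 0 counts there. A higher background of genomic or unspliced reads stays open. The summed level of 1456 olfactory and vomeronasal receptor genes changed by 0.069 ± 0.18 (log2, SE), from 3.53 ± 0.074 to 3.76 ± 0.74 CPM (SD), a spread that covers both no change and the median rise. A response of the cells to irradiation, the factor of the design, is also open and untested.

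The next pattern was the fall of tumour-cell transcripts in MNPs with the AREG− partner. RNA carried over from a knockout line that differs from its parent is a candidate explanation. LLC-dominant genes made up 72.7% of the 55 falls of 2-fold or more in EGFR+ MNPs and 6.03% of tested genes (Fisher's exact test, two-sided, p = 3.6e-37), and 58.5% of the 41 falls in EGFR− MNPs (p = 2.3e-19). As the whole source, RNA in the proportions of untreated LLC cells is argued against. In EGFR+ MNPs the 40 fallen LLC-dominant genes lost a median of 2.49% ± 0.600 (SE) of their LLC level. The 10 lowest LLC genes over 100 CPM outside these falls reached 0.341% (Thbs2) to 1.47%. In EGFR− MNPs 24 genes lost 1.49% ± 0.209, against 0.284% to 1.38%. That median lay within its SE of the highest share, but all 24 lost more than the lowest, which such RNA cannot exceed. A smaller amount of tumour RNA stays open as a part. All 887 LLC-dominant genes changed by a median of -0.188 (SE 0.179 between libraries), the fallen genes by -1.36. The MNPs' own RNA can mask a loss there. Neither co-cultured LLC cells nor the AREG− line was measured, so carry-over from cells of another profile and a response of the MNPs to lost AREG stay open for these genes, untested.

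Another pattern was a trend with transcript length, which RNA quality or a biological change in long or short transcripts can give, and the correction cannot separate these. Removing it lowered the median change of oxidative phosphorylation genes with the AREG− partner in EGFR+ MNPs from 0.201 to 0.0874 (SE 0.0219), so the trend may account for part of it. As the whole cause it is argued against, since limma's camera still gave an adjusted p = 1.4e-04 (2.7e-05 unadjusted) after the removal, against an adjusted p = 1.6e-12 before. With an estimated correlation the list was not called before or after (adjusted p = 0.258 and 0.186), so the argument rests on the preset correlation and on the corrected median. The 151 interaction calls without replicate 3 of EGFR− MNPs with the AREG+ partner (139 higher and 12 lower, median length 8963 against 3222 nucleotides over tested genes) came to 6 with the trend removed, 1 of them among the 151, as their median change in the called direction went from 0.50 to 0.24 (log2) and their median SE from 0.10 to 0.083.

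Other splits of the libraries were counted for each comparison. For the single comparisons 6 libraries make 10 splits, too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes, and the real and the highest other count were 5459 and 0 for irradiation, 1606 and 0 and 496 and 2 for the AREG− partner in EGFR+ and EGFR− MNPs, and 1720 and 21 and 598 and 0 for the MNP genotype with the AREG+ and AREG− partner. For changes of 2-fold or more these were 470 and 0, 110 and 0, 76 and 0, 72 and 1, and 46 and 0. For the interaction the real count was 0, so 100 of 100 drawn splits gave at least as many by construction, which says nothing about chance. The highest other counts were 255 genes, and 22 with 2-fold change. These splits reassigned the partner within each genotype, which put part of the effect of the partner itself into the interaction of some. The 44 other splits that carried none of it called 0 genes with edgeR. Of 48 that carried 0.667 of it 1 called any, at most 2. Of 7 that carried 1.33 times it 5 called any, with a median of 1, and the one with 255 was among them. Its calls thus came with a structure of the samples that the design names, the partner groups, and why it exceeded the other 6 was not tested.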

How the results depend on the processing

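The settings without LLC-dominant genes, length trend or farthest libraries (by the chi-square between repeats) were chosen after the data were seen. Counts of called genes moved by more than 1.5 times as follows, and the cause was not tested except where fewer genes or libraries enter by construction. The filter of 5 CPM left 29 changes of 2-fold or more for irradiation, 21 and 20 for the AREG− partner in EGFR+ and EGFR− MNPs, and 13 and 10 for the MNP genotype with the AREG+ and AREG− partner, because low genes were not tested. DESeq2 called 786 genes for the AREG− partner in EGFR− MNPs and 964 for the genotype with the AREG− partner. With only the compared groups in the fit, the genotype called 657 genes with the AREG+ and 936 with the AREG− partner. Removing the length trend left 1024 genes for the AREG− partner in EGFR+ MNPs. Leaving out LLC-dominant genes left 59 and 48 changes of 2-fold or more for the AREG− partner in EGFR+ and EGFR− MNPs.

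Without the farthest library of 3 groups, the AREG− partner in EGFR− MNPs called 1217 genes, the genotype 3731 with the AREG+ and 2334 with the AREG− partner (81 of 2-fold or more), and the interaction 427 (5 of 2-fold or more). Removing the length trend as well gave 1313, 2640, 2495 (84 of 2-fold or more) and 40 (1 of 2-fold or more) in the same order, and 73 changes of 2-fold or more for the AREG− partner in EGFR+ MNPs. Both responses to the AREG− partner correlated by 0.67 (at least 5 CPM) and 0.12 (no filter).

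Leaving out 1 library at a time gave 4223 to 6318 genes for irradiation (395 to 488 of 2-fold or more). For the AREG− partner it gave 731 to 1177 (67 to 124) in EGFR+ and 234 to 451 (53 to 72) in EGFR− MNPs. For the genotype it gave 453 to 3400 (32 to 97) with the AREG+ and 302 to 725 (32 to 51) with the AREG− partner, and 0 to 151 (0 to 1) for the interaction. Areg in LLC cells lay between -0.21 and -0.072 and Egfr between the genotypes with the AREG+ partner between -0.37 and -0.081 (log2). The correlation of partner and genotype effects lay between 0.365 and 0.583, and that of both responses to the AREG− partner between 0.366 and 0.417. Without replicate 1 of EGFR+ MNPs with the AREG+ partner, 3 lists turned in test and median: neutrophil markers with the AREG− partner in EGFR+ MNPs to 0.0746 (range -0.114 to 0.0746), and in the interaction MHC class II genes to 0.105 (-0.135 to 0.105) and neutrophil markers to -0.138 (-0.138 to 0.0948). Medians changed sign while the test kept its direction for interferon-stimulated genes between the genotypes with the AREG+ partner (0.0175, call lost, without EGFR−/AREG+ replicate 1) and dendritic cell markers with the AREG− partner in EGFR− MNPs (-0.032, call lost, without EGFR−/AREG− replicate 3). That of classical monocyte genes between the genotypes with the AREG− partner went to -0.0062 and -0.0028, called, without EGFR+/AREG− replicate 2 or 3. The cause was not tested.

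Replicate numbers did not pair the libraries: same-numbered libraries of different groups correlated by -0.028 to 0.053 in LLC cells and -0.039 to 0.087 in MNPs. With a replicate block the counts were 5987, 1619, 533, 1662, 630 and 0 in the order of the comparisons, each within 1.5 times. Of 602 results for named genes the block weakened 9 below and lifted 1 above the threshold, DESeq2 1 and 5, limma-voom 12 and 1, DESeq2-type size factors 9 and 0, and no filter 15 and 1. Counted per result and library left out, single libraries left 3511 results on their side of the threshold, weakened 516 below it, lifted 11 above it and turned 0. Of 180 list results an estimated correlation weakened 79, the block 1 (and lifted 1), DESeq2-type size factors 2, and no filter 3 (and lifted 2). Counted per list result and library left out, single libraries left 1186 on their side, weakened 55, lifted 28 and turned the test of the 3 given above. Depth limits what can be said of the lowest genes, such as Epgn.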

Other observations

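Some transcripts higher in LLC cells than MNPs rose with the AREG− partner. The keratin gene Krt8, at 69.1 CPM in untreated LLC cells, rose in EGFR+ MNPs from 2.20 ± 0.59 to 5.65 ± 0.28 CPM (SD; edgeR adjusted p = 3.7e-04). Of the 55 rises of 2-fold or more, 11 (20%) were in LLC-dominant genes (Fisher's exact test, two-sided, p = 3.8e-04), against 40 of 55 falls. By contrast Adgre4 and Clec7a had 0 counts in untreated LLC cells, and Il1a and Ccl17 stood at 0.016 and 0.061 CPM there.

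Values of the genotype comparison with the AREG+ partner that follow were computed after the data were seen. The 21 neutrophil markers changed by a common -0.33 (log2), with a heterogeneity Q of 11.001 per degree of freedom (20 degrees), and 1 of them, Stfa3, passed the threshold upward. Within 20 Mb of Lyz2 and Egfr lay 3.09% of called genes and 2.34% of tested genes (Fisher's exact test, two-sided, p = 0.0373). Lyz2 itself fell by 8.68 ± 0.21 (log2, SE).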
